A study of Mus musculus with 6 samples.

How the data were processed

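RNA of the descending colon of wild-type and Muc2-/- mice was measured by sequencing of polyadenylated RNA with paired-end Illumina reads, with 3 libraries in each of 2 groups. Groups and replicate numbers were taken from the sample titles. The titles speak of crypts, and the protocols of colon tissue. The labels give no batch, sex, time of collection, strand setting or description of the mutated allele. The titles number the replicates without saying how many animals each holds, and p-values measure the spread between these libraries.

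The authors deposited a table of counts per gene, whole numbers that are not normalized, and a table of FPKM. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build mm10 are named in the submitters' processing notes, without role or order. The FPKM values, per the file headers, were found to equal counts divided by the listed gene length and by the library total times a size factor, here within 0.121% of the DESeq2 median-of-ratios factor, from 0.860 to 1.14. The table holds 435 unnamed loci. Of 52133 gene identifiers shared with GENCODE M21, 1546 had the same start and end and 51549 the same width, so the coordinates are those of another assembly than the one named and are printed as the count table gives them. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

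The counts were tested with edgeR 4.0.16 in R 4.3.3 with statmod 1.5.0: TMM factors, the default filter on low counts (a minimum count of 10 and a total of 15), a quasi-likelihood fit with genotype alone, and Benjamini-Hochberg adjustment at 0.05. CPM are counts scaled to the library total times the TMM factor, and SD are over the 3 libraries of a group. Log2 CPM for scores and components used a prior count of 2. Single measures were compared by the exact two-sided permutation test over 20 arrangements, whose smallest p is 0.1. Counting intervals of 95% and floors of 3 counts cover counting error only. Replicates were compared by chi-square over genes, which gave 26.5 to 166 per degree of freedom, so all were kept as separate samples.

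The 47 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Some genes belong to several lists. Lists with at least 5 tested members went through camera in limma 3.58.1 at a preset correlation of 0.01, and beside it camera with an estimated correlation and fry. Genes were named by this rule: Muc2; up to 12 protein-coding genes with the largest called change each way, at 5 CPM or more in a group and with no overlap of the groups, leaving out predicted genes and immune receptor segments; up to 4 called members of each topic list, or else the 2 with the highest mean; and up to 3 called members of each cell type or pathway list, or else the 1 with the highest mean. Results for some named genes and 1 list are not reported here. Genes outside this rule were named after their values were seen, apart from the clock genes of a test in the closing section.

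The alternatives were RLE, upper-quartile and no composition factors, no filter or a stricter one (1 CPM in 3 libraries and 50 counts), DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a minimum of 1 FPKM in 3 libraries, the replicate number as a block, protein-coding genes only, removal of immune receptor and mitochondrial genes, each library left out, an adjusted p under 0.01, and a log2 fold change over 1. Muscle covariate, muscle gene removal and the omission of 2 libraries together were added after seeing the data. The procedure was tested on simulated counts for this comparison, with 15771 genes tested and 200 changed singly, beside the cytokine and chemokine list shifted as a whole. The 200 were drawn from genes with a mean of at least 5 CPM, so the shares below leave out genes with lower counts. Counts were drawn for each gene by itself, without effects shared across genes, so the shares below hold for such data only. It recovered 13.4% of genes changed 2-fold, 79.1% of those changed 4-fold and 98.5% of those changed 16-fold, and 9 of its 142 calls were unchanged genes.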

Results

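RNA from the descending colon of mice aged 12 weeks was sequenced in 6 libraries, 3 from wild-type C57BL/6 mice and 3 from Muc2-/- mice. Muc2 encodes the gel-forming mucin of the colonic mucus layer, and mice without it are used as a model of chronic colitis. The series title names sphingolipid metabolism, filamentous actin and the epithelial barrier, and gene lists on these topics were tested beside lists for cell types and pathways. The sample titles speak of crypts, whereas the protocols describe pieces of colon tissue. Total counts were 16395432, 18016672 and 20336459 in wild-type 1, 2 and 3, and 17465636, 17273046 and 16627761 in Muc2-/- 1, 2 and 3. The table held 55849 genes, of which 16107 had enough counts to be tested.

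The libraries of each group differed among themselves. The first principal component of log2 CPM held 51.6% of the variance, with wild-type 1 at one end and Muc2-/- 2 at the other. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.931 to 0.965 within wild-type, from 0.933 to 0.978 within Muc2-/- and from 0.866 to 0.960 between the groups. Mitochondrially encoded genes took 8.98%, 5.30% and 3.49% of the counts in wild-type 1, 2 and 3, and 3.50%, 1.04% and 3.30% in Muc2-/- 1, 2 and 3 (exact permutation test, two-sided p = 0.2, where 0.1 is the smallest possible). The rank correlation across genes between length and the deviation from the mean library was 0.154, 0.0907 and 0.0369 in wild-type 1, 2 and 3 and -0.0126, -0.245 and 0.0248 in Muc2-/- 1, 2 and 3 (exact permutation test, two-sided p = 0.1, the smallest possible).

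Muc2 itself, on chromosome 7 from 141276583 to 141308430 in the coordinates of the count table, was counted in every library. It stood at 2480, 6977 and 2629 CPM in wild-type 1, 2 and 3, and at 757, 1021 and 942 CPM in Muc2-/- 1, 2 and 3. The means were 4029 ± 2555 CPM and 907 ± 136 CPM (SD, n = 3 each), 4.44-fold lower in Muc2-/- with no overlap. The log2 fold change was -2.15 (SE 0.47), and the adjusted p of edgeR's quasi-likelihood test was 0.103, not past 0.05. DESeq2 gave 6.77e-05, and without wild-type 3 edgeR gave 0.0286. The labels do not say which part of the gene the mutation removes, so these residual counts do not by themselves check the genotype.

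The comparison of Muc2-/- with wild-type colon asks which transcripts differ in the mutant at this age. In the fit of all 6 libraries the largest rise among the called genes was that of Clca4b, a member of a family of chloride channel regulators, on chromosome 3 from 144616682 to 144638290. It lay at 1.88, 2.29 and 2.34 CPM in wild-type and reached a mean of 1376 ± 1039 CPM (log2 fold change 9.30, SE 0.79, adjusted p = 0.0206). Transcripts of secreted defence proteins rose too. Slpi, a leukocyte protease inhibitor, went from 10.3 ± 6.05 CPM to 299 ± 12.9 CPM (log2 fold change 4.86, SE 0.43, adjusted p = 0.0206). Pglyrp1, a peptidoglycan recognition protein, went from 246 ± 7.82 CPM to 912 ± 175 CPM (log2 fold change 1.89, SE 0.24, adjusted p = 0.0456). The mast cell protease gene Mcpt2 went from 0.168 ± 0.117 CPM to 12.0 ± 2.01 CPM (log2 fold change 6.08, SE 0.54), and the metalloproteinase gene Mmp10 from 0.106 ± 0.0593 CPM to 4.99 ± 1.13 CPM (log2 fold change 5.49, SE 0.58). In total 17 genes were higher and 3 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg over 16107 genes).

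Members of the Ly6 family on chromosome 15 were among the genes that rose. Ly6a (74866726 to 74869880), which encodes the surface antigen Sca-1, went from 216 ± 60.8 CPM to 1793 ± 383 CPM (log2 fold change 3.05, SE 0.33, adjusted p = 0.0286). Ly6c1 (74915867 to 74920679) went from 16.1 ± 4.70 CPM to 282 ± 176 CPM (log2 fold change 4.13, SE 0.49, adjusted p = 0.0454). Gml (74685301 to 74690664) had 1 count over the wild-type libraries and 388 over the Muc2-/- libraries, a ratio of 469 with a 95% interval of 83.8 to 18590 that covers counting error only. Several of the called genes have near copies with which reads can be shared, so their values are uncertain. The copies, named after the values were seen, had log2 fold changes of 7.60 (Gml2), 2.24 (Ly6c2), 6.04 (Mcpt1) and 0.26 (Clca4a), none past the threshold (edgeR adjusted p 0.0550, 0.0927, 0.0550 and 0.762).

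Among the other called genes, Marcksl1, a substrate family member of protein kinase C that binds actin, went from 28.8 ± 6.21 CPM to 195 ± 61.7 CPM (log2 fold change 2.76). Pde9a, a cyclic GMP phosphodiesterase, went from 181 ± 11.8 CPM to 778 ± 98.1 CPM (2.10), and Nfkbiz, an inducible regulator of NF-kappaB target genes, from 29.0 ± 4.30 CPM to 102 ± 23.1 CPM (1.81). The 3 lower genes were Slc30a10, Dbp and Gm29216. Slc30a10, a manganese exporter, fell by 3.61 on the log2 scale (SE 0.36, from 14.1 ± 4.02 CPM to 1.15 ± 0.0965 CPM). Dbp, a clock-controlled transcription factor, fell by 2.32 (SE 0.30, from 125 ± 16.2 CPM to 25.1 ± 9.90 CPM). Gm29216, a pseudogene on chromosome 1 named after its values were seen, fell by 3.45 (from 378 ± 179 CPM to 34.6 ± 6.04 CPM). Its counts in wild-type 1, 2 and 3 (9627, 8014 and 3817) were in the order of the mitochondrial share. So were those in Muc2-/- 1, 2 and 3 (696, 452 and 528). At like shares in wild-type 3 (3.49%) and Muc2-/- 1 (3.50%), however, it stood at 182 and 41.4 CPM. The 6 neighbouring pseudogenes, none past the threshold in edgeR, had log2 fold changes from -1.62 to -0.74. Adjusted p in edgeR lay between 0.0286 and 0.0456 for the called genes of this paragraph.

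**Figure D1:**
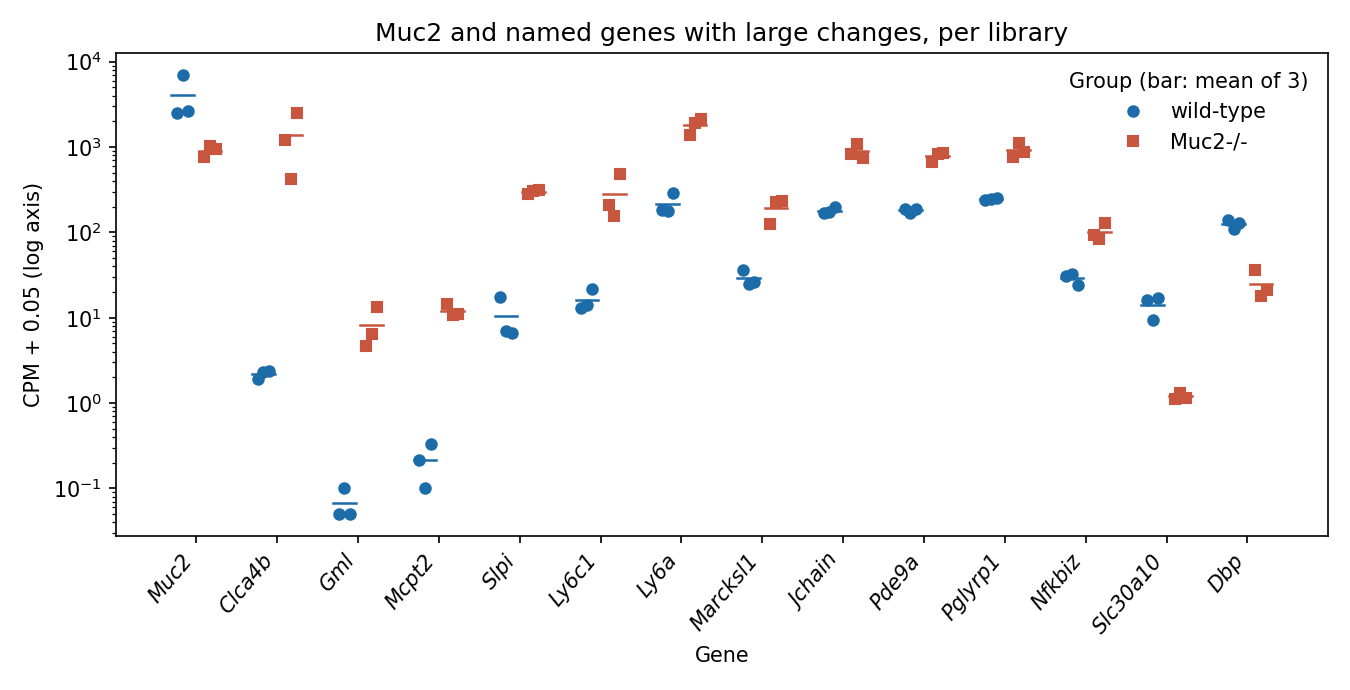
CPM plus 0.05, on a log axis, for Muc2 and named genes with large changes; each point is 1 library (circles wild-type, squares Muc2-/-) and each bar the mean of 3. The groups do not overlap in any gene shown, which the naming rule required of all but Muc2. Clca4b lies between 1.88 and 2.34 CPM in wild-type and between 422 and 2484 CPM in Muc2-/-.

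The number of called genes moved with single libraries. edgeR called 1 higher and 0 lower without wild-type 1, 0 and 0 without wild-type 2 (2426 genes at an unadjusted p under 0.05), and 272 higher and 954 lower without wild-type 3. It called 4 and 1 without Muc2-/- 1, 18 and 0 without Muc2-/- 2, 1 and 0 without Muc2-/- 3, and 1 and 0 with both wild-type 1 and Muc2-/- 2 left out, a choice made after seeing the data. All 20 genes kept their direction in these fits. DESeq2 called 659 higher and 1193 lower, all 20 among them. At an unadjusted p under 0.05 there were 3379 genes in edgeR, where 805 are expected by chance, and the groups did not overlap in 28.5% of the tested genes, where chance gives 10%. Both chance values ignore effects that many genes share within a library. Splits of the libraries that mix the genotypes gave from 44 to 1969 genes at an unadjusted p under 0.05. These splits hold the genotypes in unequal numbers on each side, so part of a genotype difference stays in them.

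Of 47 gene lists, 45 had at least 5 tested members and were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. At an adjusted p under 0.05, 20 lists shifted up and 8 down in Muc2-/-. With an estimated correlation 0 lists were called, and the smallest adjusted p was 0.105. At the preset correlation, splits of the libraries that mix the genotypes also called 9 to 24 lists, so calls are not confined to the genotype grouping. Such splits still hold the genotypes in unequal numbers on each side, so they do not show what is called without a genotype difference. The rotation test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 7 up and 3 down. Over all genes edgeR called members of the regenerative, antimicrobial, plasma cell, mast cell, fibroblast and clock lists. In each other list it called 0 members.

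**Figure D2:**
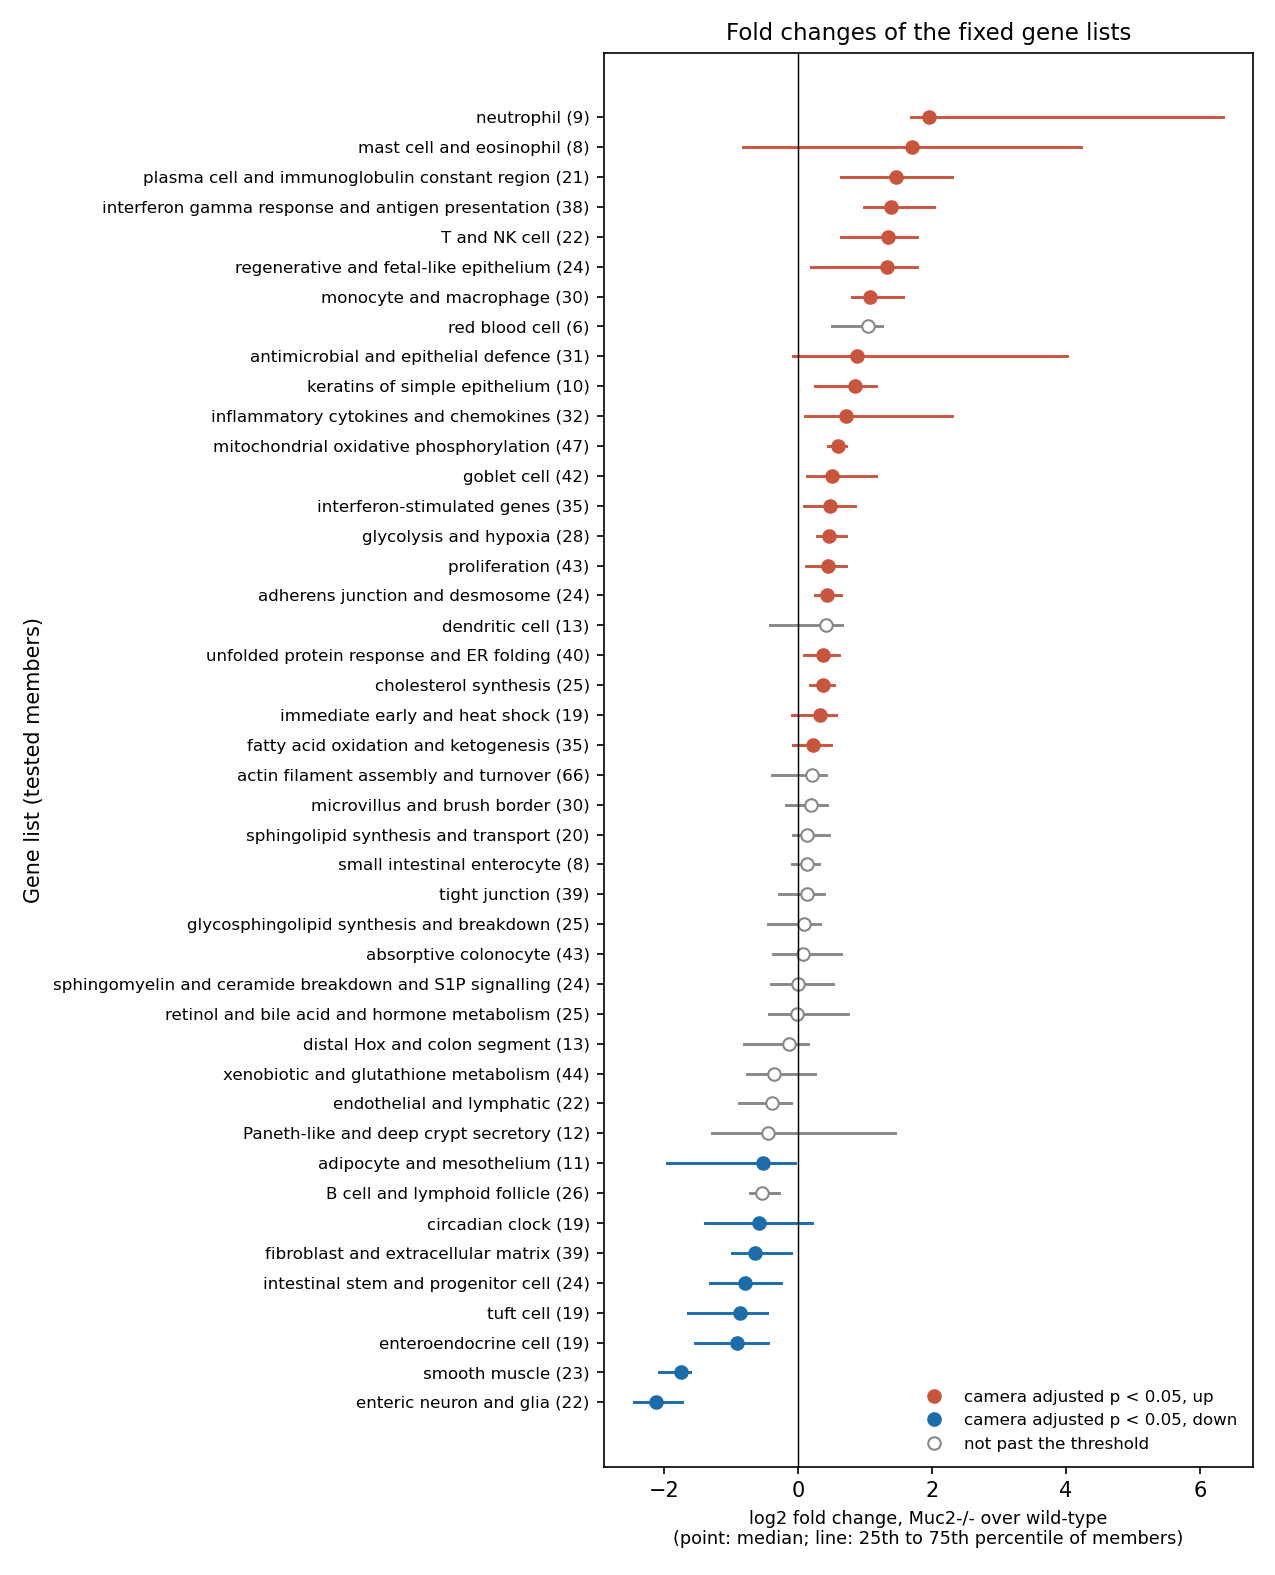
Median log2 fold change (points) and 25th to 75th percentile of the members (lines) of tested lists, Muc2-/- over wild-type, with filled points where camera's adjusted p at the preset correlation was under 0.05. The list of enteric neurons and glia lies lowest, at -2.12, and the neutrophil list highest, at 1.95.

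Plasma cell genes were higher in Muc2-/-. Igha, the constant region of the immunoglobulin A heavy chain, went from 513 ± 132 CPM to 3206 ± 724 CPM (log2 fold change 2.65, SE 0.33). Jchain, which joins IgA into dimers, went from 180 ± 16.2 CPM to 886 ± 183 CPM (2.30, SE 0.25), and the light chain gene Iglc1 from 17.9 ± 3.49 CPM to 65.7 ± 11.6 CPM (1.88, SE 0.23). Igkc (2.46), named after its value was seen, was the other of 4 list members that rose. Of 21 tested members 10 were higher when adjusted over the list alone, with a median log2 fold change of 1.46 (camera adjusted p = 6.69e-14; adjusted p = 0.105 with an estimated correlation). Ighv7-3, a variable segment outside the list and also named after its value was seen, rose by 4.69 on the log2 scale. Immunoglobulin and T cell receptor genes together took 0.109% ± 0.0228 of the counts in wild-type and 0.525% ± 0.0217 in Muc2-/- (exact permutation test, two-sided p = 0.1, the smallest possible, n = 3 each). The light chain constant genes are near copies of each other, so their single values are uncertain.

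Lists of innate immune cells shifted up. Of 23 listed neutrophil genes 9 had enough counts to be tested. All 9 had a positive log2 fold change (median 1.95), 8 of them higher when adjusted over the list alone, 8 unadjusted and 7 in DESeq2. Cd177, a neutrophil surface glycoprotein, had 180 ± 81.4 CPM in wild-type and 532 ± 140 CPM in Muc2-/-. S100a9, a calcium-binding protein of neutrophils named after its value was seen, had 0 counts in wild-type and 1652 in Muc2-/-, so it passed the filter through Muc2-/- alone. It was at least 666-fold higher against a floor of 3 counts over the group, and the list's median is 1.95 with it at that bound. Cd177 had 4318, 4117 and 1835 counts in wild-type 1, 2 and 3, where S100a9 had 0. The wild-type counts of Cd177 therefore need not come from neutrophils. Of 8 mast cell and eosinophil genes, Mcpt2 rose over all genes, and 4 were higher and 1 lower when adjusted over the list alone (median 1.69). Of 30 monocyte and macrophage genes, 13 were higher and 1 lower when adjusted over the list alone, 17 and 1 unadjusted and 12 and 1 in DESeq2 (median 1.08), and Lyz2 had 142 ± 92.9 CPM and 157 ± 45.7 CPM. Camera gave 1.72e-11 for neutrophil, 2.32e-05 for mast cell and 2.97e-11 for macrophage genes, with an adjusted p of 0.211, 0.105 and 0.262 with an estimated correlation.

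Lymphocyte lists were less uniform. T and NK cell genes shifted up (22 genes, median 1.35, camera 2.59e-05), with adjusted p = 0.388 with an estimated correlation. None passed when adjusted over the list alone, and 8 were higher unadjusted and 3 in DESeq2. The B cell list (26 genes) was not called (camera 0.630). Its median was -0.55 and its mean -0.48, while camera pointed up and the deposited FPKM gave a median above 0. Ighm stood at 75.5, 11.6 and 4.63 CPM in wild-type 1, 2 and 3 and at 29.7, 7.66 and 37.8 CPM in Muc2-/- 1, 2 and 3. Without wild-type 1 the median was 2.14 and camera's adjusted p 3.71e-11. No B cell gene passed in edgeR over the list alone or unadjusted, nor in DESeq2. Dendritic cell genes (13 genes, median 0.41, camera 0.193) were called only without wild-type 1 (0.00181) among the single libraries left out. None passed when adjusted over the list alone, 1 was higher unadjusted and 1 in DESeq2, and Bst2 had 23.9 ± 1.94 CPM and 44.3 ± 14.9 CPM.

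Inflammatory and interferon genes shifted up. All 38 genes of the interferon gamma and antigen presentation list had a positive log2 fold change (median 1.39), 26 were higher when adjusted over the list alone, 29 unadjusted and 23 in DESeq2. H2-K1, a class I heavy chain, had 1298 ± 304 CPM in wild-type and 2038 ± 172 CPM in Muc2-/-. Of 32 cytokine and chemokine genes (median 0.71), 11 were higher and 0 lower when adjusted over the list alone, 13 and 2 unadjusted and 11 and 0 in DESeq2, and Ccl6 had 266 ± 35.2 CPM and 333 ± 75.8 CPM. Of 35 interferon-stimulated genes (median 0.47), 8 were higher when adjusted over the list alone, 12 unadjusted and 8 in DESeq2, and Irf7 had 116 ± 22.0 CPM and 101 ± 17.2 CPM. Camera gave 2.38e-19, 6.68e-08 and 3.01e-05 for these lists, with adjusted p = 0.283, 0.130 and 0.285 with an estimated correlation. With the smooth muscle score as a covariate, chosen after seeing the data, the interferon-stimulated median was 0.09 and that call ended. The other lists of this paragraph kept their calls.

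Genes of the antimicrobial and regenerative lists shifted up. The antimicrobial list shares members with the neutrophil list, S100a9 among them, so the shifts of these lists are not independent. In the antimicrobial list (31 genes, median 0.88, camera 1.05e-10, adjusted p = 0.105 with an estimated correlation), Slpi and Pglyrp1 rose over all genes, and 13 members were higher and 1 lower when adjusted over the list alone. In the list of regenerative and fetal-like epithelial genes (24 genes, median 1.32, camera 6.05e-14, adjusted p = 0.105 with an estimated correlation), Ly6a rose over all genes, and 14 were higher and 1 lower when adjusted over the list alone. Among the 14, named after their values were seen, Areg had 24.3 ± 7.18 CPM and 107 ± 35.6 CPM, and Hbegf had 18.6 ± 5.05 CPM and 61.2 ± 8.13 CPM. Both encode ligands of the epidermal growth factor receptor.

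Intestinal stem cell genes shifted down. Of 24 tested members 12 were lower and 0 higher when adjusted over the list alone, 12 unadjusted and 10 in DESeq2 (median -0.79, camera 1.28e-05, adjusted p = 0.262 with an estimated correlation). Prom1, the member with the highest mean, had 295 ± 110 CPM and 475 ± 191 CPM. The mean log2 CPM of the list was 5.30, 5.12 and 4.82 in wild-type 1, 2 and 3, the same order as that of the smooth muscle list below. In Muc2-/- 1, 2 and 3 it was 4.50, 4.18 and 4.45, not in the order of that list. Lgr5, a marker of crypt base stem cells named after its value was seen, had 6.06 ± 2.16 CPM in wild-type and 2.44 ± 0.355 CPM in Muc2-/-. Proliferation genes went up as a list (43 genes, median 0.44, camera 9.97e-05, adjusted p = 0.512 with an estimated correlation). None passed when adjusted over the list alone, 12 were higher unadjusted and 4 in DESeq2, and Hmgb2 had 85.0 ± 15.7 CPM and 141 ± 44.1 CPM.

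Among secretory lineages, goblet cell genes, with Muc2 left out, shifted up (42 genes, median 0.50, camera 2.19e-06, adjusted p = 0.285 with an estimated correlation). Within wild-type the list's mean log2 CPM (6.29, 6.73 and 7.02) ran opposite to that of the smooth muscle list. Within Muc2-/- (7.48, 7.64 and 7.41) it did not. With a muscle covariate the median was 0.16 and the call ended. The muscle score did not overlap between the groups, so the covariate can also take up a change by genotype. Adjusted over the list alone, 4 were higher, namely Galnt3, C1galt1, Sytl2 and Muc1, named after their values were seen. Unadjusted 10 were higher and 1 lower, and in DESeq2 6 were higher. Zg16, a goblet cell lectin, had 1765 ± 2767 CPM in wild-type and 9727 ± 2685 CPM in Muc2-/-, and passed without wild-type 3 (log2 fold change 5.86, edgeR adjusted p = 0.0148) but not with it (2.46, 0.312). Enteroendocrine genes shifted down (19 genes, median -0.91, camera 1.46e-04, adjusted p = 0.105 with an estimated correlation). Of these 6 were lower when adjusted over the list alone, 9 unadjusted and 6 in DESeq2, and Cpe, a prohormone carboxypeptidase, had 327 ± 172 CPM and 109 ± 25.2 CPM. Tuft cell genes shifted down (19 genes, median -0.87, camera 1.71e-04, adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone Dclk1 and Sh2d6, named after their values were seen, were lower, 8 were lower unadjusted and 4 in DESeq2, and Cd24a had 465 ± 124 CPM and 378 ± 129 CPM. Within wild-type the mean log2 CPM of the enteroendocrine (4.10, 3.85 and 3.54) and tuft cell lists (2.88, 2.81 and 2.03) was also in the order of the smooth muscle list. Within Muc2-/- 1, 2 and 3 the smooth muscle list had 6.61, 6.13 and 5.72. Neither the enteroendocrine (3.07, 2.87 and 3.03) nor the tuft cell list (1.52, 1.71 and 1.66) kept that order there. With the muscle covariate the tuft cell median was -0.20 and that call ended, while the enteroendocrine call stayed. The Paneth-like list (12 genes, camera 0.377, up) was not called, and its median of -0.45 and mean of 0.02 differed in sign. Adjusted over that list alone 4 were higher and 2 lower, unadjusted 4 and 2 and in DESeq2 4 and 1, and Spink4 had 827 ± 307 CPM and 2127 ± 1082 CPM.

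Genes of the muscle wall were lower in Muc2-/- and varied within wild-type. All 23 smooth muscle genes had a negative log2 fold change (median -1.76), 20 were lower when adjusted over the list alone, 21 unadjusted and 20 in DESeq2. All 22 neuron and glia genes were negative (median -2.12), with 17 lower when adjusted over the list alone, 17 unadjusted and 16 in DESeq2. Camera gave 2.67e-14 for muscle and 7.98e-13 for neuron genes, and both had an adjusted p = 0.285 with an estimated correlation. Des, the muscle intermediate filament desmin, stood at 4576, 2529 and 1179 CPM in wild-type 1, 2 and 3 and at 959, 1380 and 573 CPM in Muc2-/- 1, 2 and 3. The mean log2 CPM of the smooth muscle list was 8.72, 8.02 and 6.96 in wild-type 1, 2 and 3 and 6.61, 6.13 and 5.72 in Muc2-/- 1, 2 and 3 (exact permutation test, two-sided p = 0.1, the smallest possible). Erbb3, the neuron and glia member with the highest mean, had 202 ± 38.0 CPM and 173 ± 90.3 CPM.

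**Figure D3:**
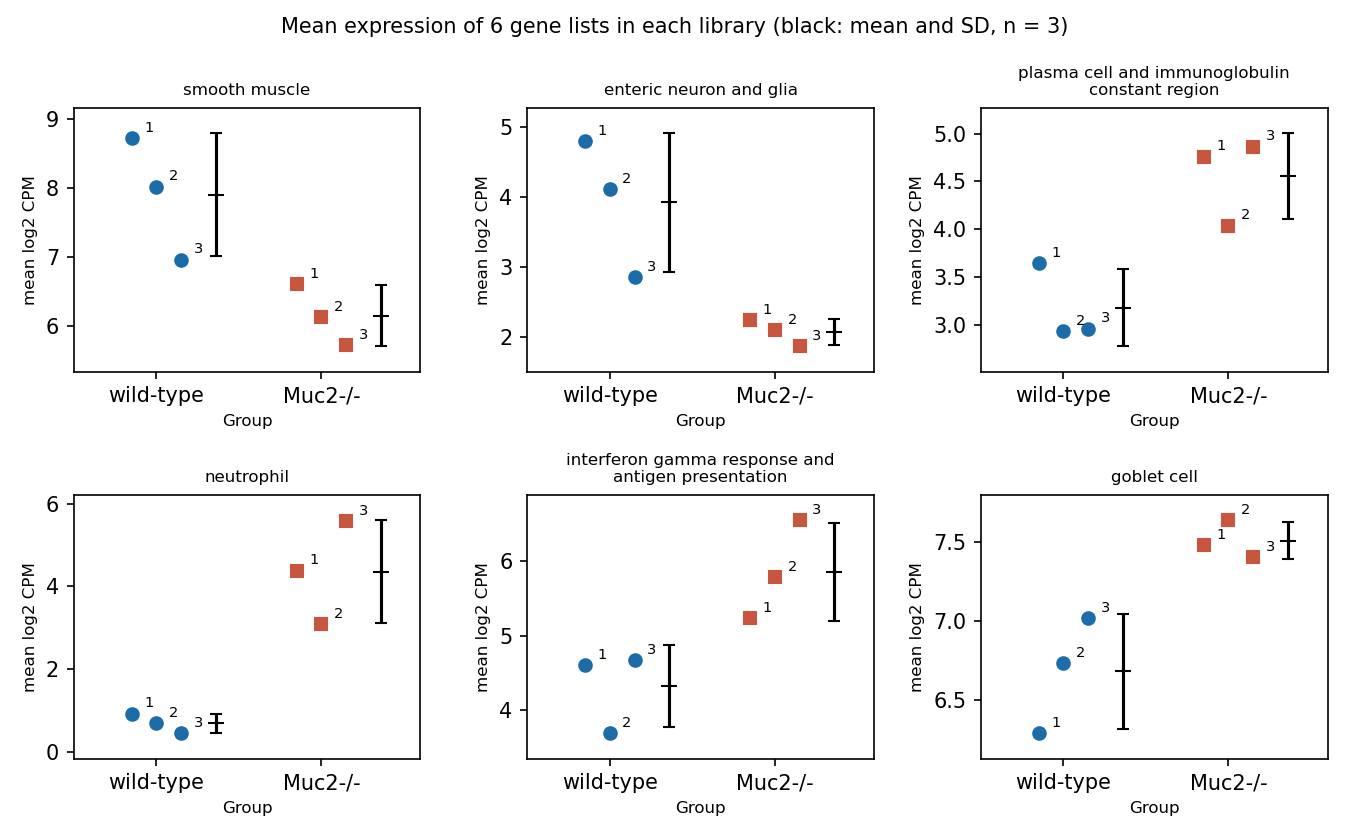
Mean log2 CPM of 6 gene lists in each library, with the replicate number beside each point and the mean and SD of 3 libraries in black. Smooth muscle scores run from 6.96 to 8.72 in wild-type and from 5.72 to 6.61 in Muc2-/-, and neutrophil scores from 0.45 to 0.92 in wild-type and from 3.09 to 5.58 in Muc2-/-.

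Other stromal lists were lower or not called. Fibroblast and matrix genes shifted down (39 genes, median -0.64, camera 0.00547, adjusted p = 0.630 with an estimated correlation), with 8 lower and 2 higher when adjusted over the list alone. Mmp10, which rose over all genes, belongs to this list. The call was lost without wild-type 1 (0.348) and without Muc2-/- 2 (0.0526). Adipocyte and mesothelial genes shifted down (11 genes, median -0.52, camera 0.0447, adjusted p = 0.630 with an estimated correlation). Plin4 and Msln, named after their values were seen, were lower when adjusted over the list alone, 4 were lower unadjusted and 3 in DESeq2, and Fabp4 had 17.3 ± 6.03 CPM and 19.7 ± 8.20 CPM. That call was lost without wild-type 1 (0.0907), wild-type 2 (0.202, median 0.07) or Muc2-/- 3 (0.0996), and also with upper-quartile factors, library totals, DESeq2, log2(FPKM + 1) with or without a filter, and protein-coding genes alone. Endothelial genes (22 genes, median -0.39, camera 0.0631) were not called, and among the single libraries left out passed without wild-type 2 (0.0302) or Muc2-/- 2 (0.0437). None passed when adjusted over the list alone, 5 were lower unadjusted and 2 in DESeq2, and Plvap had 26.8 ± 6.93 CPM and 38.0 ± 3.38 CPM.

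The sphingolipid lists were not called, and no member passed in edgeR over all genes or adjusted over the list alone. Sphingolipid synthesis and transport (20 genes, median 0.14, camera 0.169) held Degs2, a dihydroceramide desaturase and hydroxylase, at 152 ± 35.7 CPM in wild-type and 322 ± 190 CPM in Muc2-/-, and Sptlc2, a subunit of serine palmitoyltransferase, at 175 ± 49.8 CPM and 270 ± 28.2 CPM. Unadjusted 3 were higher, DESeq2 called 0, and the list passed without wild-type 2 (0.0464, median 0.08). The list of ceramide breakdown and sphingosine 1-phosphate signalling (24 genes, camera 0.761, up) had a median of -0.00 and a mean of -0.09. Smpdl3a, an acid sphingomyelinase-like phosphodiesterase, had 255 ± 80.9 CPM and 516 ± 47.8 CPM and passed without wild-type 3 (edgeR adjusted p = 0.0305), and Plpp2 had 198 ± 38.1 CPM and 305 ± 58.0 CPM. Unadjusted 4 were higher and 2 lower, and DESeq2 called 1 each way. Glycosphingolipid genes (25 genes, camera 0.761, up) had a median of 0.08 and a mean of -0.16. Psap, the saposin precursor, had 715 ± 18.4 CPM and 816 ± 44.0 CPM, and Hexa, a lysosomal hexosaminidase, means of 134 CPM and 211 CPM. Unadjusted 3 were higher and 3 lower, and DESeq2 called 1 each way.

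The list of actin genes was not called. Actin filament assembly and turnover (66 genes, camera 0.277, up) had a median of 0.20 and a mean of -0.13. It passed on FPKM with no filter (0.0161) and with both wild-type 1 and Muc2-/- 2 left out. Actb had 3598 ± 530 CPM and 4912 ± 624 CPM, and Actg1 had 2261 ± 77.6 CPM and 2306 ± 206 CPM. Adjusted over the list alone, and named after their values were seen, Capg, which caps filament ends, was higher (log2 fold change 2.45, SE 0.40), and Tmod2 (-2.66, SE 0.49) and Svil (-2.20, SE 0.49) were lower. Unadjusted 9 were higher and 11 lower, and in DESeq2 6 and 9.

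Adherens junction and desmosome genes shifted up (24 genes, median 0.43, camera 5.79e-04, adjusted p = 0.334 with an estimated correlation). The list's mean log2 CPM within wild-type (6.39, 6.73 and 6.74) ran opposite to that of the smooth muscle list. Within Muc2-/- (6.92, 6.77 and 7.10) it did not. With a muscle covariate, chosen after seeing the data, the median was 0.01 and the call ended, which does not tell muscle content from genotype. Epcam had 1950 ± 357 CPM and 3001 ± 626 CPM, and Cdh1, which encodes E-cadherin, 880 ± 211 CPM and 1705 ± 400 CPM. None passed when adjusted over the list alone, 7 were higher and 1 lower unadjusted, and 3 and 1 in DESeq2. Tight junction genes (39 genes, median 0.13, camera 0.146) were not called, with Cldn7 at 905 ± 159 CPM and 1692 ± 761 CPM and Cldn3 at 602 ± 154 CPM and 743 ± 56.2 CPM. Adjusted over the list alone, and named after their values were seen, Cldn4 (48.8 ± 15.2 CPM and 163 ± 12.7 CPM) and Cldn8 were higher and Jam2 was lower. Unadjusted 6 were higher and 3 lower, and in DESeq2 3 and 2. Microvillus genes (30 genes, median 0.19, camera 0.169) passed without wild-type 2 (0.0320) or wild-type 3 (0.0403). Ezr had 1019 ± 195 CPM and 914 ± 395 CPM and Cdhr5 820 ± 170 CPM and 1038 ± 199 CPM, no member passed over the list alone, and 2 were higher and 1 lower unadjusted and 0 in DESeq2.

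Keratins shifted up (10 genes, median 0.84, camera 0.00263, adjusted p = 0.262 with an estimated correlation). Krt7 and Krt23, named after their values were seen, were higher when adjusted over the list alone, 3 unadjusted and 3 in DESeq2, and Krt8 had 5882 ± 2110 CPM and 11190 ± 2872 CPM. Genes of absorptive colonocytes (43 genes, median 0.08, camera 0.0970) were not called, with Lypd8 at 7534 ± 2523 CPM and 11487 ± 4539 CPM. They passed, upward, without wild-type 2 (0.00233), wild-type 3 (4.06e-04) or Muc2-/- 3 (0.0430). Trim15, named after its value was seen, was higher when adjusted over the list alone, 6 were higher and 2 lower unadjusted, and 3 and 1 in DESeq2. Scaling to library totals moved the median of all tested genes by -0.19 and turned the medians of the sphingolipid synthesis, glycosphingolipid, tight junction, absorptive and small intestinal lists and the values of Actg1, Lyz2, Fabp4 and Cdx1 below 0.

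Metabolic lists shifted up with small medians and with 0 members passing when adjusted over the list alone. These were oxidative phosphorylation (47 genes, all positive, median 0.59, camera 3.94e-08), folding in the endoplasmic reticulum (40 genes, median 0.37, 2.11e-04), glycolysis and hypoxia (28 genes, median 0.46, 2.32e-05), cholesterol synthesis (25 genes, median 0.36, 3.92e-04) and fatty acid oxidation (35 genes, median 0.23, 0.0447). In that order, the adjusted p with an estimated correlation was 0.510, 0.105, 0.246, 0.456 and 0.630. Unadjusted 7, 12, 10, 5 and 2 genes were higher, and in DESeq2 1, 3, 6, 3 and 2, while 1 fatty acid oxidation gene was lower unadjusted. Atp5b had 1672 ± 447 CPM and 1991 ± 56.5 CPM, Pdia3 570 ± 74.3 CPM and 959 ± 209 CPM, and Ldha 1391 ± 339 CPM and 2379 ± 432 CPM. Hmgcs1 had 318 ± 65.9 CPM and 508 ± 163 CPM. The oxidative phosphorylation score was 8.74 in Muc2-/- 2 and 7.42 to 8.08 in the other libraries. Over wild-type 1, 2 and 3 the oxidative phosphorylation (7.42, 7.91 and 7.95) and cholesterol scores (5.87, 6.19 and 6.50) ran opposite to the smooth muscle list. Over Muc2-/- 1, 2 and 3 neither the oxidative phosphorylation (8.08, 8.74 and 8.01) nor the cholesterol score (6.61, 6.43 and 6.62) did. With the muscle covariate the oxidative phosphorylation and glycolysis calls ended and the cholesterol and fatty acid oxidation medians turned below 0, while the folding call stayed. The fatty acid oxidation call was lost without wild-type 1 (0.670) and without Muc2-/- 2 (0.349), and also with library totals, a stricter filter, DESeq2 and filtered FPKM.

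Xenobiotic genes (44 genes, median -0.36, camera 0.260) were not called, and among the single libraries left out passed only without wild-type 1 (8.03e-04), and Abcc2 was lower when adjusted over the list alone. Unadjusted 4 were higher and 8 lower, and in DESeq2 2 and 3. Retinol and bile acid genes (25 genes, median -0.03, mean 0.08, camera 0.273, up) passed without wild-type 3 (0.00835), with Nr1h4 higher and Cyp26b1 lower when adjusted over the list alone, and 5 higher and 1 lower unadjusted and 3 and 1 in DESeq2. Abcc2, Nr1h4 and Cyp26b1 were named after their values were seen. Adh1 had the highest mean of both lists, at 889 ± 446 CPM and 660 ± 146 CPM. Markers of the distal colon (13 genes, median -0.13, camera 0.408), red blood cells (6 genes, median 1.04, 0.277) and small intestinal enterocytes (8 genes, median 0.13, 0.761) were not called. No member of these 3 lists passed when adjusted over the list alone or in DESeq2, and 1 distal colon gene and 1 red blood cell gene were lower unadjusted. Cdx1 had 445 ± 125 CPM and 506 ± 79.4 CPM, Bpgm 52.6 ± 6.82 CPM and 68.7 ± 6.48 CPM, and Fabp2 243 ± 293 CPM and 321 ± 350 CPM. The pancreatic acinar list had 2 tested members and the sex-linked list 4, too few for camera. Cela1 had 303 ± 157 CPM and 286 ± 97.7 CPM, and Clps, named after its value was seen, was lower when adjusted over the list alone.

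Of the lists kept as technical checks, immediate early and heat shock genes shifted up (19 genes, median 0.33, camera 0.00373, adjusted p = 0.334 with an estimated correlation), a call lost without wild-type 3 (0.0534). Zfp36 and Fosb, named after their values were seen, were higher when adjusted over the list alone, 6 unadjusted and 4 in DESeq2. Clock genes shifted down (19 genes, median -0.59, camera 2.12e-04, adjusted p = 0.285 with an estimated correlation). Dbp fell over all genes, and 1 member was higher and 10 lower when adjusted over the list alone.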

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

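The fits with a muscle covariate, with muscle, neuron and matrix genes removed, and with wild-type 1 and Muc2-/- 2 both left out were chosen after seeing the data. The 20 called genes kept their direction in each setting that tested them, but the counts moved with most choices. Against 17 higher and 3 lower, there were 22 and 5 with RLE factors, 14 and 3 with upper-quartile factors, 7 and 1 with library totals, 384 and 815 with no filter, 17 and 3 with a stricter filter, 659 and 1193 in DESeq2, 11 and 2 in limma-voom, 37 and 9 on log2(FPKM + 1), 31 and 8 on log2(FPKM + 0.1), and 3 and 0 on FPKM with no filter (3603 at an unadjusted p under 0.05). Protein-coding genes alone gave 13 and 2, and removal of immune receptor and mitochondrial genes 10 and 2. An adjusted p under 0.01 gave 0 and 0, and a log2 fold change over 1 gave 17 and 3. Leaving out each library gave 0 to 272 higher and 0 to 954 lower. The muscle covariate gave 0 and 0 in edgeR (434 at an unadjusted p under 0.05), with 1 parameter more in 6 libraries. The smooth muscle score did not overlap between the groups (6.96 to 8.72 in wild-type, 5.72 to 6.61 in Muc2-/-). The covariate can therefore take up a change by genotype, and a call lost with it does not tell muscle content from genotype. Mcpt2 went from 6.08 (SE 0.54) to 5.78 (SE 0.88) with it, Slpi from 4.86 (SE 0.43) to 6.00 (SE 0.66) and Slc30a10 from -3.61 (SE 0.36) to -3.76 (SE 0.53), where the calls ended with wider errors. Gml went from 8.38 (SE 0.89) to 6.35 (SE 1.35), Ly6c1 from 4.13 (SE 0.49) to 2.97 (SE 0.74) and Ly6a from 3.05 (SE 0.33) to 2.29 (SE 0.48), with smaller folds and wider errors, and Gm29216 from -3.45 (SE 0.41) to -1.93 (SE 0.41), with a smaller fold alone. Removal of muscle, neuron and matrix genes gave 16 and 3, and omission of wild-type 1 and Muc2-/- 2 gave 1 and 0. Apart from the smaller samples and gene sets, the cause was not tested.

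The Muc2 log2 fold change passed the threshold with no filter (-2.14, adjusted p = 0.00915), in DESeq2 (-2.13, 6.77e-05) and with the replicate block (-1.98, 0.0397), and ranged from -2.40 to -1.50 over single libraries left out (adjusted p from 0.0286 to 0.289). The replicate number as a block gave 225 higher and 448 lower. Same-numbered libraries deviated together with correlations of 0.0937, 0.281 and 0.0606 across genes. Wild-type 1 and 2 correlated best with the Muc2-/- library of their own number and wild-type 3 did not, which does not decide on pairing. The numbers were not taken as pairs because the labels do not say that they pair mice. Lists called numbered 28, 0 with an estimated correlation, 10 by fry, and 27 to 31 over single libraries left out. With the muscle covariate the medians of microvillus (-0.27), absorptive (-0.43), fibroblast (0.54), smooth muscle (0.17, by construction), adipocyte (2.50), small intestinal (-0.23), fatty acid oxidation (-0.17), cholesterol (-0.12) and retinol genes (-0.50) turned sign or direction of the test, as did fatty acid oxidation (-0.13) with wild-type 1 and Muc2-/- 2 left out. Medians of lists called in neither fit also changed sign or direction of the test: sphingolipid synthesis (-0.09), tight junction (-0.10) and red blood cell genes (0.11) with the covariate, and red blood cell (-0.01) and small intestinal genes (-0.34) with the 2 libraries left out. With the covariate the adherens junction (0.01), goblet cell (0.16), interferon-stimulated (0.09), oxidative phosphorylation (0.15), glycolysis (0.23), neuron and glia (0.01) and tuft cell lists (-0.20) lost their calls, and with the 2 libraries left out the fibroblast, adipocyte and oxidative phosphorylation lists did, while with the covariate the stem cell (-0.32) and enteroendocrine lists (-0.79) kept theirs. Further lists gained a call: actin genes on FPKM with no filter and with the 2 libraries left out, endothelial genes in limma-voom and on FPKM with no filter, absorptive genes with no filter and with the replicate block, Paneth-like genes with the covariate, and dendritic, B cell and xenobiotic genes with the covariate and with the 2 libraries left out. The cause was not tested. Over the alternatives fixed beforehand, list results were the same in 859 cases, lost their call in 65 and gained one in 18, and named genes were the same in 1063, lost their call in 108, gained one in 15 and moved in 5. In simulated counts 13.4% of 2-fold changes were recovered among genes with a mean of at least 5 CPM, which limits what 3 libraries a group can show.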

Other observations

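The tests on gene length, on clock genes and on other genes between the Ly6 genes were written before their results were seen, and the other tests here were chosen after the results were seen. Some goblet cell genes differed widely within wild-type. Zg16 stood at 106, 230 and 4959 CPM in wild-type 1, 2 and 3 and at 10744, 11756 and 6682 CPM in Muc2-/- 1, 2 and 3. Tff3, a trefoil peptide of goblet cells, stood at 75.5, 80.2 and 1440 CPM and at 2267, 3161 and 1342 CPM. Clca1 stood at 432, 354 and 5867 CPM and at 4845, 1807 and 2974 CPM, while Agr2, which folds mucins, lay between 845 and 1270 CPM in wild-type and between 883 and 1136 CPM in Muc2-/-. None of these passed the threshold, and they were named after their values were seen. Sprr2a3 had 388 ± 101 CPM in wild-type and 1273 ± 135 CPM in Muc2-/-, and Sprr1a 5.56 ± 4.19 CPM and 48.6 ± 16.2 CPM, and neither passed the threshold. These 2 genes, and the 2 mitochondrial genes that follow, were also named after their values were seen. In Muc2-/- 2, mt-Nd4 stood at 207 CPM against 2588 to 6147 CPM in the other libraries, while mt-Nd6, on the opposite strand, stood at 1097 CPM against 796 to 1880 CPM.

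Smooth muscle and neuron lists were lower in Muc2-/-. A bias by gene length is argued against, since other genes matched on length and level had a median log2 fold change of 0.034 (quartiles -0.20 and 0.21), against -1.98 for the 45 listed genes. Unequal amounts of muscle wall in the pieces may account for it: the smooth muscle score ranged over wild-type by 1.01 times the difference between the group means. That account also called for a wild-type library that reaches the Muc2-/- scores, and none did (lowest wild-type 6.96, highest Muc2-/- 6.61). The muscle content of the pieces and the genotype cannot be told apart, because the labels give no measure of the wall.

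The 17 higher genes were also weighed. Less muscle wall would raise all other genes alike. The 90th percentile of 144 epithelial genes was 0.95 and their median 0.21, below each of the 17 genes. With 3 libraries a group mostly large changes are called, so genes picked by their calls would lie above an unselected list in any case. The comparison therefore does not decide on this cause. Muc2-/- 2 alone is argued against, since 10 of the 17 were still called without it. Of the 10 splits of the libraries into 3 and 3, the only 1 with 20 called genes was the real one (highest other 1), and the only 1 with 28 called lists was the real one (highest other 24), but the splits are too few for a share under 0.05. The other splits, which mix the genotypes, still called 9 to 24 lists. They hold the genotypes in unequal numbers on each side, so they are no measure of calls without a genotype difference. With an estimated correlation 0 lists were called, so list calls at the preset correlation do not by themselves point to genotype. A difference by genotype stays open.

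Clock genes were weighed as the last pattern. Genes that peak with Dbp had a median log2 fold change of -0.69, and Arntl, Clock, Npas2 and Nfil3, which peak opposite to it, one of 0.39. A different time of day at collection may account for this. None of the opposite-phase genes passed in edgeR over all genes (1, Nfil3, at an unadjusted p under 0.05), the list result had been seen before, and a change of the clock by genotype stays open and untested.

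Neighbourhoods on chromosomes were examined as hypotheses. Strain alleles carried along with the Muc2 mutation could alter genes near it, but 29 of 131 tested genes within 10 Mb had an unadjusted p under 0.05 against 3349 of 15975 elsewhere (Fisher's exact test, two-sided p = 0.747, odds ratio 1.07, 95% interval 0.683 to 1.64), which leaves the question open. The 14 tested Ly6 and Gml genes on chromosome 15 from 74596167 to 75471330 had a median of 2.03, with 11 positive and 3 negative, and 0.424% of 15816 windows of as many neighbouring genes reached that median. Since the family was looked at because some members rose, this decides nothing. The 2 other tested genes between them had a median of 0.23, too few to tell whether the neighbourhood moves as a whole.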
